A study of Mus musculus with 4 samples.

How the data were processed

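H3K4me3 chromatin immunoprecipitation sequencing was done on heart of female mice, with 2 pools of 2 biosamples and 2 technical replicates per pool, and fragments of 200 to 600 bp, per the labels. The labels name a protocol for frozen tissue. The deposited files were 4 peak lists in narrowPeak format on mm10. Per the deposited library notes, 1 list was called pseudoreplicated for pool G, 1 for pool H and 1 for both pools, and 1 list for both pools was called replicated. Both technical replicates of a pool point to the same alignment, so there were no values per library, and technical replicates could not be compared. The peak caller, its version, and its threshold were not given in the sources used here. The labels name a possible control experiment without saying whether it was used for the peaks. Alignments and signal tracks were not used here.

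Of the deposited columns, 2 were used. The signal value of each peak, deposited by the authors, was read as a fold enrichment, a ratio to a control. This reading is an assumption: the values are above 1 and not whole, the deposited notes name signal tracks of fold change over control, and the files do not name the column. The -log10 q value of each peak is also the authors', and 667 peaks of the replicated list had q over 0.05, so that q was not the threshold of that list. Every peak end lay within its chromosome's length in the reference genome of the same build.

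Genes were taken from GENCODE M21. A promoter was 1000 bp on either side of any start of a protein-coding transcript, and a gene was occupied where a peak overlapped it by at least 1 bp. Its fold enrichment was that of the highest such peak. Peaks no more than 1000 bp apart were joined into domains, and a gene's width was that of its widest promoter domain. A promoter was high-CpG where the window of any start had an observed over expected CpG ratio of at least 0.6 and a GC share of at least 0.5. Random positions for the background started 3000000 bp into each chromosome and ended 100000 bp before its end. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used.

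The gene lists, 27 in all, were written before the data were examined, as were the tests and the rule for the genes to name, and 26 of them have protein-coding members outside chromosome Y. Occupancy was tested with Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists at 0.05. Widths and fold enrichments of lists with at least 3 occupied members were placed among 10000 random lists of occupied genes. The genes named were, per list, the 2 occupied members with the highest fold enrichment and the member with the widest domain, the unoccupied members of lists at least 80% occupied and the occupied members of lists at most 25% occupied, up to 6; over all genes, the 15 widest domains and the 10 highest fold enrichments present in all 4 lists; and Xist, Actb, Myh6, Alb and the Y-linked genes as controls. Not every gene the rule names is given. Other names were added after their values were seen.

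Intervals were tested on simulated data, where overlaps and joined intervals were equal to those of bedtools. On 200 simulated lists of 20 genes among 20000, Fisher's test called 86.0% of lists with raised occupancy, 98.5% of lists with lowered occupancy and 0 of the unchanged lists. Lists made wider lay in the upper 2.5% in 69.5% of cases, and unchanged lists in 2.0%. Smaller lists were not simulated.

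The alternatives were the other 3 lists, a -log10 q of at least 5, promoter windows of 500 and 2000 bp, the longest transcript only, gaps of 0 and 3000 bp, the nearest peak, an overlap of 50% of both peaks, joining before the overlap, peaks that overlap 1 peak only, the widest 2% and 10%, and CpG bounds of 0.5 and 0.7. Read depth was not given, so no interval for depth could be set, and the binomial intervals cover counting error only.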

Results

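Trimethylation of lysine 4 on histone H3 (H3K4me3), a histone mark found at active promoters, was mapped by chromatin immunoprecipitation and sequencing in heart tissue of female B6CASTF1/J mice aged 2 months. The 4 libraries came from 2 pools of tissue, named G and H in the labels, each made of 2 heart biosamples and carrying 2 technical replicates. Pools G and H were labelled biological replicates 1 and 2, and all labels named the same donor record, so nothing in them says that the pools held separate animals. No other tissue, treatment or genotype was included, and the comparisons below are between pools, between groups of genes and between chromosomes. The values were 4 peak lists on the mouse build mm10, of which the list made from both pools and called replicated is the main one. Read depth was not given in the sources used here. The signal value of a peak, read here as a fold enrichment, is the authors' own and was compared only within a list, apart from the correlation between the pools.

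The replicated list held 24996 peaks on chromosomes 1 to 19 and X, with a median width of 1021 bp and a median fold enrichment of 8.37. They covered 30.7 Mb and joined into 20113 domains when gaps of up to 1000 bp were bridged. Chromosome Y held 0 peaks in every list, and none of the 8 listed Y-linked genes, Sry and Ddx3y among them, had a promoter peak. Chromosome 11 was the most densely marked, with 16.4 peaks per Mb, and X, of the chromosomes with peaks, the least, with 4.14 peaks per Mb. Pool G's own list held 24826 peaks over 33.4 Mb and pool H's own list 21505 peaks over 26.1 Mb. The list called on both pools with pseudoreplicates held 26412 peaks, and 24037 of the replicated peaks were identical to one of them, so these 2 lists are not independent.

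Nearly all of the promoters marked in pool H were also marked in pool G. Of 21670 protein-coding genes outside chromosome Y and the mitochondrion, 13245 had a promoter peak in both pools' lists, 492 in pool G only and 32 in pool H only. Of pool H's peaks, 98.0% overlapped a pool G peak by at least 1 bp, while 76.8% of pool G's peaks overlapped one of pool H. The 5761 peaks of pool G without a partner were the weak and narrow part of that list: their median fold enrichment was 3.68 against 14.0 for pool G's shared peaks, and their median width 452 bp against 1424 bp. None of them reached a fold enrichment of 10. Over the 21084 matched peaks, the log2 fold enrichment of the 2 lists had a Pearson correlation of 0.83 and a Spearman correlation of 0.83, with an SD of the log2 difference of 0.50. These correlations are across peaks, which are not independent replicates.

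Most of the mark lay at the starts of protein-coding genes. In the replicated list 15755 peaks, 63.03% (exact 95% binomial interval 62.4% to 63.6%, counting error only), lay within 1000 bp of a protein-coding transcript start, and they made up 79.9% of the covered base pairs. Peaks placed at random on the same chromosomes reached 4.08% ± 0.128 (SD over 100 shuffles). A further 7.47% of peaks lay at starts of other genes, 4.04% in exons, 14.5% in introns and 10.96% between genes. Peaks at protein-coding starts were stronger and wider than those in introns, with a median fold enrichment of 13.4 against 3.26 and a median width of 1418 bp against 446.5 bp. In pool H's own list, the share at protein-coding starts was 72.0%.

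Of the 21670 protein-coding genes, 13657 had a promoter peak, a share of 63.02% (exact 95% binomial interval 62.4% to 63.7%). The pools' own lists gave 63.4% for pool G and 61.3% for pool H. Promoters rich in CpG were marked almost throughout: 7051 of 7294 high-CpG promoters (96.7%) were occupied, against 6606 of 14376 low-CpG promoters (46.0%), an odds ratio of 34.1. The p of this Fisher's exact test was smaller than double precision can hold. The odds ratio was 35.5 in pool G's list and 26.8 in pool H's list, and it moved most with the promoter window, to 55.8 with 500 bp and 19.04 with 2000 bp. Some heart lists were occupied without high CpG content and others in part: all 19 low-CpG sarcomere genes and all 13 low-CpG endothelial genes had a peak, against 3 of 7 low-CpG atrial genes and 5 of 10 low-CpG fetal and stress genes. Of the high-CpG Hox genes 11 had none. The most strongly enriched promoters present in all 4 lists were those of Cdipt and its antisense neighbour Cdiptos, which share a peak with a fold enrichment of 32.6, followed by Avl9 and Trim39 at 29.9, Sin3b at 29.2 and Atf4, a transcription factor of the stress response, at 28.8.

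Genes of heart muscle function and metabolism were marked almost throughout. All 24 sarcomere genes, all 24 genes of ion channels and calcium handling and all 30 genes of fatty acid use and respiration had a promoter peak. Of 25 cardiac transcription factors 24 were occupied, and the exception was Hand1, while Hand2, Gata4 and Gata6 carried some of the widest domains. The exact adjusted p was 9.6e-05 for the sarcomere list, 9.6e-05 for the ion and calcium list, 3.1e-05 for the fatty acid list and 0.000865 for the transcription factors. The tests were two-sided Fisher's exact tests against all other protein-coding genes, of which 62.98% were occupied beside the sarcomere list, with Benjamini-Hochberg adjustment over 26 lists. Genes are not replicates, so these p-values describe this tissue's list. The same 4 lists had the same occupied share in both pools' own lists.

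Genes tied to the chambers and to stress were marked in part. The ventricular list had 6 of 7 members occupied, Myh7, the slow myosin heavy chain, being the exception, and the atrial list had 7 of 11. Nppa, which encodes atrial natriuretic peptide, had no promoter peak, nor did the atrial genes Myl7, Sln and Bmp10. Of the fetal and stress genes 7 of 12 were occupied, with Nppb at a fold enrichment of 4.93 and Ankrd1 at 3.41, and Nppa, Myh7, Acta1, Ankrd2 and Fgf21 without a peak. The occupied atrial genes included Myl4 and Gja5, whose domains also reach the promoters of Cdc27 and Gpr89. None of these 3 lists passed the test against other genes, with exact adjusted p of 0.372 for the ventricular, 1.0 for the atrial and 0.834 for the fetal and stress list. With 7 members the ventricular list could not have been called higher. The 7 listed genes that escape X inactivation, all occupied, were not called either (exact adjusted p = 0.096). Nppb and the unmarked atrial, fetal and stress genes were named after their values were seen. The shares of the atrial list and of the fetal and stress list lay so close to that of other genes that their direction changed with the processing.

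**Figure D1:**
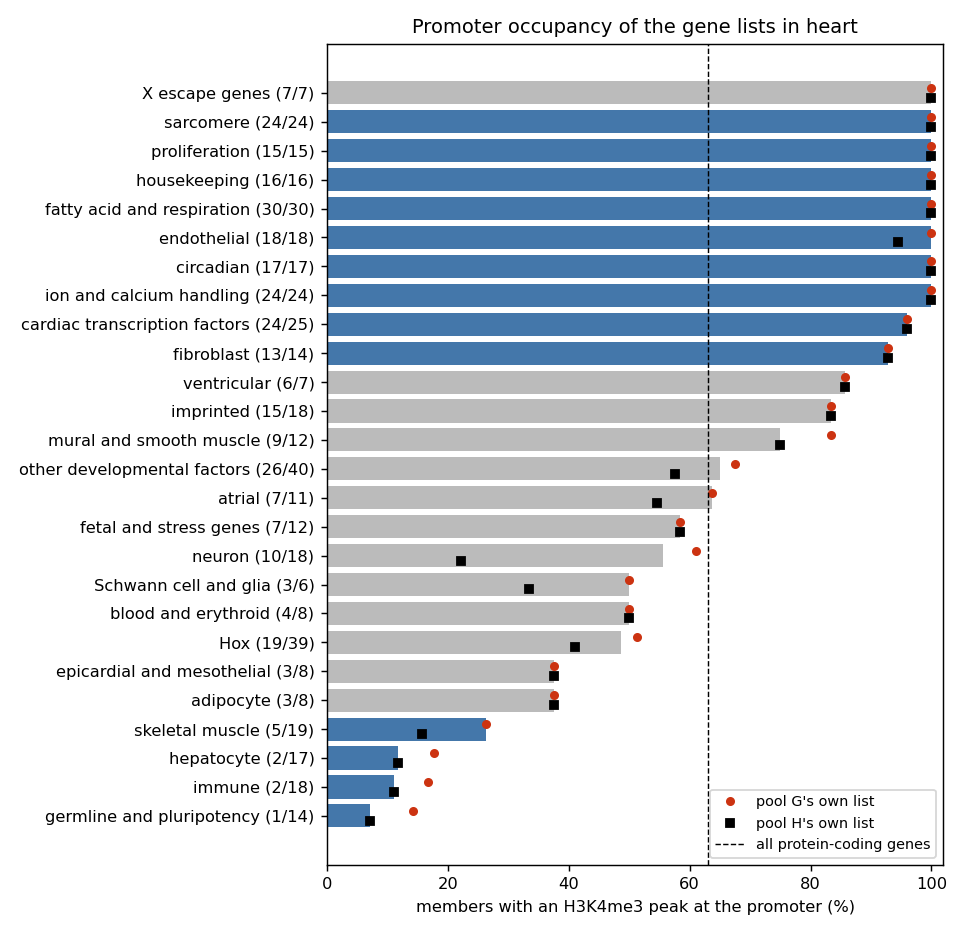
Share of each gene list's members with an H3K4me3 peak within 1000 bp of a transcript start, in percent, as bars for the replicated list (blue, adjusted p under 0.05; grey, not) with pool G's own list as circles and pool H's own list as squares; the dashed line is the share of all protein-coding genes. The germline and pluripotency list has 1 of 14 members occupied, and the sarcomere list 24 of 24.

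Markers of 3 cell types of the heart wall were each set against all other genes, and not against each other. All 18 endothelial genes were occupied in the replicated list (exact adjusted p = 0.00104) and 17 in pool H's own list (exact adjusted p = 0.0054), among them Fli1 and Ets1, both transcription factors, with fold enrichments of 21.4 and 19.05. Of the fibroblast markers 13 of 14 were occupied (exact adjusted p = 0.0475), led by Gsn at 12.8 and Fn1, which encodes fibronectin, at 10.9, and Postn was not. Mural and smooth muscle markers stood at 9 of 12, with Smtn at 16.9 and Mcam at 14.0, and did not pass the test (exact adjusted p = 0.685). The fibroblast call was lost with -log10 q of at least 5 (exact adjusted p = 0.156) and with a promoter window of 500 bp (exact adjusted p = 0.158).

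Immune, hepatocyte, germline and skeletal muscle genes were mostly unmarked. Of 18 immune genes 2 were occupied (exact adjusted p = 9.6e-05), the transcription factors Ikzf1 and Runx3, at fold enrichments of 6.25 and 4.13, while Ptprc, the pan-leukocyte gene, and Cd68, both named after their values were seen, had no peak. Of 17 hepatocyte genes 2 were occupied (exact adjusted p = 9.6e-05), Foxa3, whose domain also reaches the promoter of Sympk, and Foxa1, and the control gene Alb had no peak. Of 14 germline and pluripotency genes only Dazl was occupied (exact adjusted p = 9.6e-05), at 10.8. Of 19 skeletal muscle genes 5 were occupied (exact adjusted p = 0.00335), and the strongest, Actn3 at 22.3 and Mylpf at 15.8, shared their domains with Zdhhc24 and Tbc1d10b. These tests were not matched on promoter CpG content, and most members of these lists have low-CpG promoters. Among low-CpG members, 0 of 16 immune, 0 of 14 hepatocyte, 0 of 12 germline and 4 of 17 skeletal muscle genes were occupied. Over all genes, 46.0% of low-CpG promoters were occupied, and this difference was not tested.

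Smaller lists and the neuron list did not pass the test. Epicardial and mesothelial markers were occupied in 3 of 8 cases (exact adjusted p = 0.224), with Wt1 at a fold enrichment of 10.1 and Aldh1a2 at 6.72. Adipocyte markers also stood at 3 of 8 (exact adjusted p = 0.224), with Cidea at 9.37 and Fabp4 at 9.13, and blood and erythroid genes at 4 of 8 (exact adjusted p = 0.622), with Klf1 at 15.3 and Tal1 at 12.3. Schwann cell and glial markers were occupied in 3 of 6 cases (exact adjusted p = 0.765). A list of 6 could not have been called higher, since 7 of 7 escape genes were not (exact adjusted p = 0.096). Of 18 neuronal genes 10 were occupied (exact adjusted p = 0.740), with Elavl4 at 8.64 and Eno2 at 7.89. The neuronal share was 61.1% in pool G's own list and 22.2% in pool H's own list, where it was lower than in other genes (exact adjusted p = 0.00221). The difference between the pools was not tested.

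Genes of general cell functions were marked throughout. All 16 housekeeping genes (exact adjusted p = 0.0026), all 17 circadian clock genes (exact adjusted p = 0.00162) and all 15 proliferation genes (exact adjusted p = 0.00397) were occupied, including Mki67, a gene of dividing cells, at a fold enrichment of 14.3. Arntl, a core clock gene, stood at 26.1, Hsp90ab1 at 23.0 and the control gene Actb at 20.8, with a domain of 5540 bp. Of the imprinted genes 15 of 18 were occupied (exact adjusted p = 0.144), with Gnas at 19.4 and Cdkn1c at 15.1. The Hox genes stood at 19 of 39 (exact adjusted p = 0.120) and the other developmental transcription factors at 26 of 40 (exact adjusted p = 0.906), with Msx1 at 15.9. In pool H's own list the Hox genes were lower than other genes, with 41.0% occupied (exact adjusted p = 0.0229), and with -log10 q of at least 5 they were too, with 41.0% occupied (exact adjusted p = 0.0251).

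Among the widest promoter domains, with gaps of up to 1000 bp joined, were those of the listed heart genes Myh6, Gata6, Atp2a2, Hand2 and Gata4, and of genes in no list such as Nfib, Itpkb and Klf3. The widest lay at Myh6, the alpha myosin heavy chain of adult heart, on chromosome 14 from 54956237 to 54976555. This domain spanned the 5' part of Myh6 and the 3' part of Myh7 upstream of it. It reached into the promoter window of the predicted gene Gm17428 but ended before that gene's start at 54976933. The Myh6 domain was 20319 bp wide in the replicated list and 18018 ± 514.8 bp (SD, n = 2 pools) in the pools' own lists. Nfib followed with 16791 bp, Dll4, a Notch ligand of endothelium, with 14040 bp, Smad7 with 13872 bp, Gata6 with 13362 bp and Atp2a2, the calcium pump of the sarcoplasmic reticulum, with 12715 bp. Over the pools, Nfib measured 15051.5 ± 2527.9 bp, Gata6 13333 ± 305.5 bp and Atp2a2 10476.5 ± 911.5 bp, and Dll4 11191 ± 4116.8 bp (SD, n = 2 pools each). The Dll4 domain was 14102 bp in pool G and 8280 bp in pool H. This order rests on the joining of gaps. With none joined, Gata6 kept 13362 bp, while the widest peak overlapping the promoter window was 3457 bp at Myh6 and 6674 bp at Nfib. It was 5109 bp at Dll4, 7038 bp at Smad7 and 8100 bp at Atp2a2. The Myh6 peak ended at 54966033, inside the gene, and no peak of any list covered the gene's start at 54966927.

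**Figure D2:**
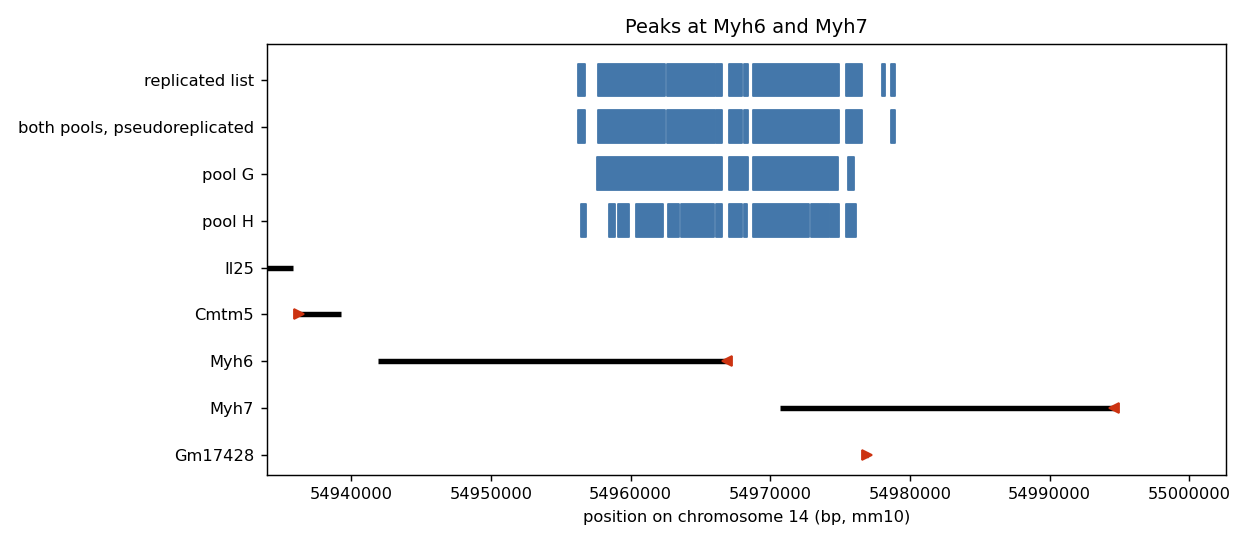
Peaks of the 4 lists (blue blocks) and gene bodies (black lines, red arrowheads at the start of the gene) along chromosome 14 at Myh6 and Myh7, in bp of mm10. The peaks from 54956237 to 54976555 in the replicated list join into 1 domain of 20319 bp, and no peak lies at the start of Myh7.

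Most lists of heart and vessel genes had domains wider than the 1799 bp median of all occupied genes. The median was 5390.5 bp for endothelial genes, 4907 bp for cardiac transcription factors, 4587 bp for sarcomere genes, 3754 bp for ion and calcium genes and 2960 bp for fatty acid and respiration genes. Each of these 5 medians lay at percentile 100 among 10000 random lists of as many occupied genes. In the pools' own lists the endothelial median was 5584.5 ± 569.2 bp and the sarcomere median 4330.75 ± 660.1 bp, against 1786 ± 149.9 bp over all occupied genes (SD, n = 2 pools). The ventricular list, with 3942.5 bp, lay at percentile 99.9, but the atrial list, with 1916 bp (percentile 61.1), and the fetal and stress list, with 1727 bp (percentile 41.6), did not stand apart. In all, 10 lists lay in the upper 2.5% and 5 in the lower 2.5%, the latter being Hox (788 bp), skeletal muscle (828 bp), neuron (884.5 bp), proliferation (1316 bp) and other developmental factors (1383.5 bp). Among the other wide lists, the mural list lay at percentile 98.9, but at 88.7 in pool H's own list, and the imprinted list at percentile 99.9, but at 97.045 in pool H's own list. The circadian list (2808 bp, percentile 99.8) and the housekeeping list (2610.5 bp, percentile 99.4) were also wide. Both stayed in the upper 2.5% in each pool's own list. The skeletal muscle list, with 3 occupied members in pool H's own list, lay at percentile 32.9 there. Over genes alone in their domain, mural (percentile 92.0), skeletal muscle (2.66) and proliferation genes (3.24) no longer stood apart by width.

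Among the widest 5% of promoter domains, those of at least 4431 bp, 5 of the wide heart and vessel lists were over-represented, and the ventricular list, with 2 of 6 (exact adjusted p = 0.115), and the mural list, with 1 of 9 (exact adjusted p = 0.625), were not. Of occupied endothelial genes 11 of 18 had such a domain (exact adjusted p = 1.2e-09), of sarcomere genes 13 of 24 and of cardiac transcription factors 13 of 24 (exact adjusted p = 2.9e-10 for each). Ion and calcium genes followed with 8 of 24 (exact adjusted p = 1e-04), fatty acid and respiration genes with 7 of 30 (exact adjusted p = 0.00318) and circadian genes with 4 of 17 (exact adjusted p = 0.0378). Among the widest members were Egfl7 with 11245 bp, Cd36, a fatty acid transporter, with 9689 bp and Per1, a clock gene, with 6161 bp. The test was Fisher's exact test, two-sided, against other occupied genes, of which 5.09% had such a domain beside the sarcomere list. The circadian call was lost with no gaps joined (exact adjusted p = 0.922), in the widest 2% (exact adjusted p = 0.178) and in the widest 10% (exact adjusted p = 0.0735). Other lists gained a call: housekeeping genes with no gaps joined (exact adjusted p = 0.0284) and with gaps of 3000 bp (exact adjusted p = 0.00756), and ventricular (exact adjusted p = 0.000302) and imprinted genes (exact adjusted p = 0.0486) in the widest 10%. Calls in 1 pool's own list only were those of fibroblast markers in pool G, with 5 of 13 (exact adjusted p = 0.00166), against 1 of 13 in pool H, and of mural markers in pool G, with 3 of 10 (exact adjusted p = 0.0394), against 1 of 9 in pool H. The ventricular list was called in pool H, with 3 of 6 (exact adjusted p = 0.00729), against 2 of 6 in pool G. Differences between the pools were not tested.

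Width and fold enrichment did not rank the gene groups alike. Sarcomere genes had a median fold enrichment of 9.75 (percentile 0.07 among 10000 random lists), ion and calcium genes 10.5 (percentile 0.27) and fibroblast markers 6.35 (percentile 0.02), against 15.3 over all occupied genes. Endothelial genes, with 11.5 (percentile 2.82), and cardiac transcription factors, with 13.5 (percentile 12.3), lay within the central 95% of random lists. Hox genes, other developmental factors and neuronal genes were both narrow and weak, with medians of 5.58, 5.05 and 4.37, while housekeeping genes had 17.9 (percentile 93.7). No list lay in the upper 2.5% by fold enrichment, and 10 lay in the lower 2.5%. Among random lists matched on promoter CpG ratio, 4 of these 10 no longer did: sarcomere (percentile 60.6), ion and calcium (5.87), mural (22.4) and fetal and stress genes (18.3). Another 3 lists entered the lower 2.5% there: cardiac transcription factors (percentile 2.04), epicardial and mesothelial (0.855) and proliferation genes (1.10). Over all 20113 domains, width and fold enrichment had a Spearman correlation of 0.73, across domains, which are not independent replicates.

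**Figure D3:**
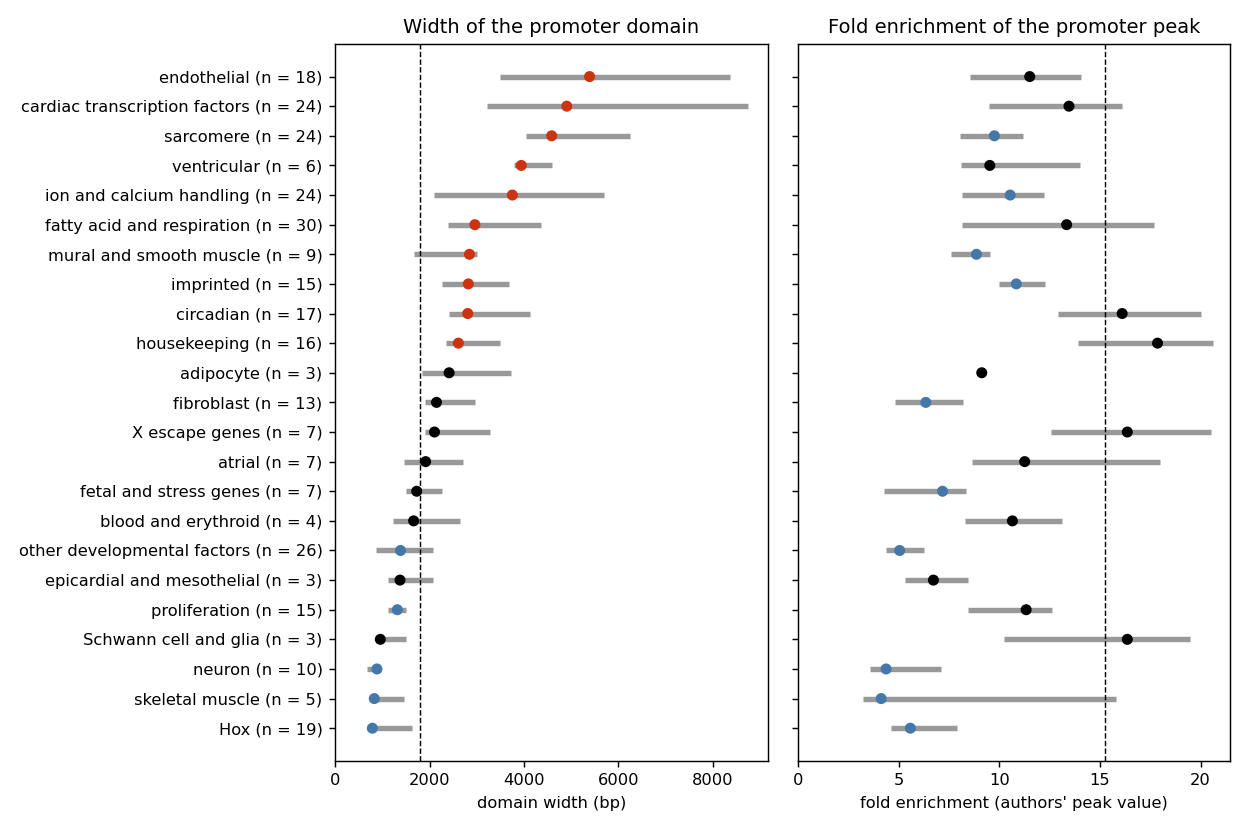
Median (point) and quartiles (grey bar) over the occupied members of each list for the width of the promoter domain in bp (left) and the authors' fold enrichment of the promoter peak (right), in the replicated list; red points lie in the upper and blue points in the lower 2.5% of random lists, and dashed lines are the medians of all occupied genes, 1799 bp and 15.3. Sarcomere genes lie to the right by width, at 4587 bp, and to the left by fold enrichment, at 9.75.

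Genes on the X chromosome were marked less often and less strongly than autosomal genes. Of 948 X-linked genes 421 (44.4%) had a promoter peak, against 13236 of 20722 autosomal genes (63.9%), an odds ratio of 0.452 (two-sided Fisher's exact test, p = 1.6e-32). This difference in occupancy was not matched on promoter CpG content. The median fold enrichment of occupied X-linked promoters was 10.4 against 15.5 on the autosomes, a ratio of 0.671, and it lay below each of 10000 random sets of as many autosomal genes, of which the lowest median was 14.0. The autosome with the lowest median, chromosome 14, stood at 14.9. The ratio was 0.701 in pool G's own list and 0.664 in pool H's own list. Xist, the RNA that coats the inactive X, had a promoter peak with a fold enrichment of 12.3 and a domain of 3701 bp.

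All 7 protein-coding genes listed as escaping X inactivation were occupied (exact adjusted p = 0.096 for the list). Ddx3x had a fold enrichment of 25.05 and a domain of 5300 bp, and Kdm6a one of 21.7 and a domain of 4004 bp. The median of the 7 genes was 16.4.

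**Figure D4:**
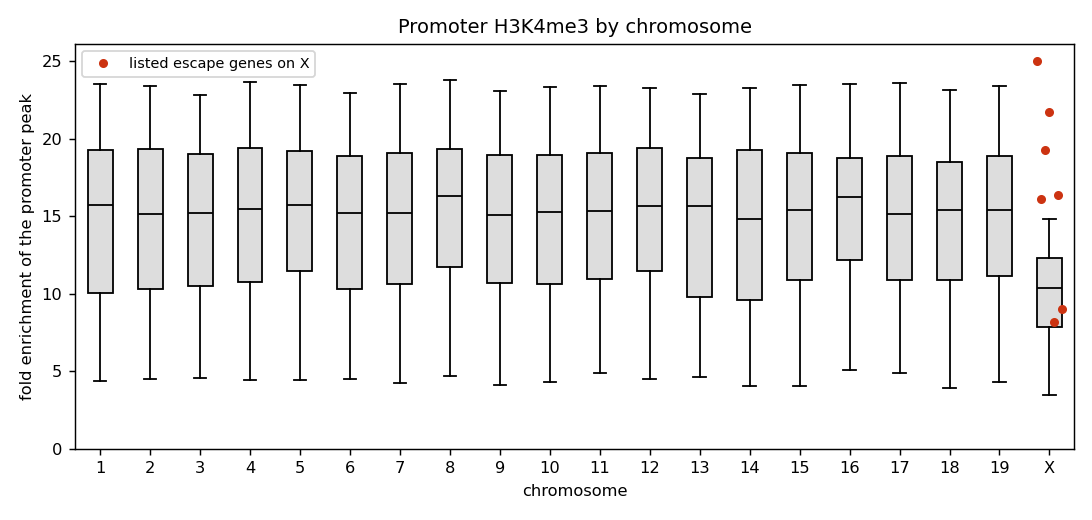
Fold enrichment of occupied protein-coding promoters by chromosome in the replicated list; boxes are quartiles with the median, whiskers span the central 90% of genes, and red points are the 7 listed escape genes. The median is 10.4 on X and between 14.9 and 16.3 on the autosomes.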

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

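The results of the main comparisons were recomputed under the alternatives planned for each, 1 choice at a time. Of the tests under other observations, the Hox test was repeated in each pool's own list. The tests over genes alone in their domain were chosen after the data were seen. No paired analysis was possible because the deposited lists hold no values per library, so the technical replicate numbers shared by the pools cannot be used. Each pool's own list stands in for leaving out the other. Over the main results, 108 of the recomputed values did not change by the measure that applied and 21 did. The measure was direction and call for a test, 1.5 times for a count and the spread between pools for most other values. The pools' own lists set that spread and are also alternatives, so an unchanged value there is in part built in. A larger spread between the pools also widens the tolerance for the other alternatives. Shares of overlap between the pools' lists were measured by the binomial interval of the main value. Correlations between these lists were measured by equality at 2 decimals. The odds ratio of CpG classes kept its direction and call but ranged from 19.04 to 55.8 over the alternatives. The number of lists with higher occupancy, 9, and with lower occupancy, 4, stayed within 1.5 times under every alternative run, though single lists gained a call 5 times and lost one 2 times. Imprinted genes gained one with a window of 2000 bp (Fisher's exact test, adjusted p = 0.0496). Escape genes gained one over genes alone in their domain (Fisher's exact test, adjusted p = 0.0441). The other gains were those of neuronal and Hox genes given above, and the losses those of fibroblast markers. Among the widest domains, the circadian list lost its call 3 times and other lists gained one 7 times: housekeeping with gaps of 0 and of 3000 bp, ventricular in pool H's own list and in the widest 10%, imprinted in the widest 10%, and fibroblast and mural in pool G's own list. The direction changed 8 times, always in lists with no call. The atrial share fell below that of other genes in pool H's own list (54.5%), with the longest transcript only (45.5%), with a window of 2000 bp (63.6%) and over genes alone in their domain (55.6%). The other developmental factors did so in pool H's own list (57.5%, against 67.5% in pool G's), with -log10 q of at least 5 (60.0%) and with the longest transcript only (57.5%), and the fetal and stress list rose above other genes over genes alone in their domain (58.3%).

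The pools' own lists gave 62.0% to 72.0% of peaks at promoters, 61.3% to 63.4% of genes occupied, a ratio of X to autosomal fold enrichment of 0.664 to 0.701, 2.77% to 2.98% of peaks on X and a Spearman correlation of width and fold enrichment of 0.67 to 0.74. With -log10 q of at least 5 these were 74.1% of peaks at promoters, 61.4% of genes, 2.99% on X and 0.65. With the longest transcript only, 55.8% of peaks lay at promoters and 60.6% of genes were occupied. With gaps of 3000 bp, and over genes alone in their domain, 3 lists in place of 5 lay in the lower 2.5% by width.

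The share of pool H's peaks found in pool G was 80.1% with 50% of both peaks and 98.9% with -log10 q of at least 5. The share of pool G's peaks found in pool H was 69.4% and 79.6% under these, and 80.8% when peaks were joined first. The Pearson correlation was 0.84 with -log10 q of at least 5 and 0.94 with peaks that overlap 1 peak only, where Spearman's was 0.94. A rule of 50% of both peaks can only lower a share. For the other shifts the cause was not tested. Depth per library is unknown and limits what the absence of a peak in 1 pool shows.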

Other observations

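In this part, the gene families, the Hox split, the test of a mark confined to part of the cells and the test of escape genes were chosen after the values were seen.

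Gene families picked by symbol ranged from nearly unmarked to marked throughout. Of 1134 olfactory receptor genes 4 had a promoter peak, with 2 in pool G's own list and 0 in pool H's, and of 329 vomeronasal receptor genes 1, Vmn1r4, at a fold enrichment of 17.9. All 78 genes of the mitochondrial ribosome and all 46 genes with symbols starting in Nduf were occupied. Of the latter, 45 were occupied in pool H's own list. Most, but not all, genes named Nduf encode subunits of respiratory complex I or its assembly factors. Among the Nduf genes, Ndufa4 and Ndufs1 are also in the fatty acid and respiration list. Of 67 histone genes 56 were occupied, of 394 genes named Zfp 342, and of 57 genes of the protocadherin clusters 19. Of 53 keratin genes named Krt, 2 were occupied, Krt10 and Krt222.

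Hox genes of high number were occupied less often in the replicated list and in pool G's own list. In the replicated list, of the genes numbered 1 to 9, 18 of 27 were occupied, against 1 of 12 numbered 10 to 13, the genes used nearest the tail of the embryo (two-sided Fisher's exact test, odds ratio 22.0, p = 0.00125). In pool G's own list the counts were 19 of 27 and 1 of 12 (exact test, odds ratio 26.1, p = 0.000432). In pool H's own list they were 14 of 27 and 2 of 12, which did not pass the test (exact test, odds ratio 5.38, p = 0.0758). The split was chosen on these same data, and neighbouring Hox genes are not independent. The replicated list was made from both pools, so the pools' tests do not repeat it independently. These p-values therefore only describe the lists. A single strong peak was called in pool H alone, on chromosome 13 from 119487806 to 119488561, with a fold enrichment of 16.2.

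Most lists of heart and vessel genes lay in wide domains, as did the circadian, housekeeping and imprinted lists. In the replicated list the atrial, the fetal and stress and the fibroblast lists did not, among unmatched random lists. Matched on promoter CpG ratio, the fibroblast list lay at width percentile 98.4, the atrial list at 72.6 and the fetal and stress list at 66.4. Unmatched, the fibroblast list lay at 99.2 in pool G's own list and at 44.3 in pool H's. Counting all lists, 8 lay in the upper 2.5% by width with no gaps joined and 9 over genes alone in their domain, against 10 in the main setting. For the sarcomere, ion and calcium, cardiac factor and endothelial lists, 3 technical explanations were tested. Against random lists matched on promoter CpG ratio, the lowest of the 4 width percentiles was 100. With no gaps joined it was 99.8, and over genes alone in their domain it was 100. Each value lies in the upper 2.5%, which for these 4 lists argues against CpG content, joining of peaks and shared domains as the whole cause. The lists were chosen because they were wide, and the design gives no biological explanation that could be tested; that the width is biological is a hypothesis found and tested on the same data.

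Promoters of some cell type lists were low in fold enrichment. The Schwann cell and glial (percentile 60.4), blood and erythroid (11.4), adipocyte (9.82) and epicardial and mesothelial lists (4.1) were not in the lower 2.5%. On the sarcomere, ion and calcium, endothelial, fibroblast and mural lists, 2 explanations were set against each other. The endothelial list was included although its unmatched percentile of 2.82 was not in the lower 2.5%. Matched on promoter CpG ratio, the highest of the 5 percentiles was 60.6, for sarcomere genes, and the endothelial list rose to 52.0. The mural list lay at 22.4, the ion and calcium list at 5.87 and the fibroblast list at 2.33, and the cardiac factors, outside these 5 lists, at 2.04, so CpG content may account for part of the pattern. Of the cell type lists outside these 5, neuron (0.03), skeletal muscle (0.57) and epicardial and mesothelial genes (0.855) lay in the lower 2.5% when matched. Schwann cell and glial (76.8), blood and erythroid (26.4) and adipocyte genes (21.7) did not. A mark confined to part of the cells was predicted, after the values were seen, to leave nearly all of the 5 lists in the lower 2.5%. Only 1 of the 5 lists lay there, so this prediction was not met. The bound does not follow from the explanation, and the matched random lists can hold cell type genes themselves. The explanation therefore also stays open.

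Promoters on X were lower in fold enrichment, and promoter CpG content was tested first. The X median was at percentile 0 among autosomal sets matched on CpG ratio. The median of these sets was 14.3, against 10.4 on X and 15.5 over all occupied autosomal promoters. This argues against promoter CpG content as the whole cause of the lower fold enrichment. Occupancy on X was not matched on CpG ratio. If the mark lay on 1 of 2 X chromosomes, genes that escape inactivation should stand higher. The median of the 7 escape genes was 16.4 against 10.2 for the other 414 X-linked genes, at percentile 100 of random X-linked sets. These sets were not matched on promoter CpG content or breadth of expression, so the test cannot tell escape from such traits. A mark mostly on the active X is a candidate explanation; it was found and tested on the same data, and the lists do not separate the parental alleles.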
